A study of Homo sapiens with 20 samples.

How the data were processed

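Poised Enhancer Capture Hi-C was done on 20 libraries of 10 conditions, with 2 libraries per condition. The deposited matrix held 1 score column per condition, and the labels assigned both libraries of a condition to the same column, with 0 columns unmatched. The unit was the CHiCAGO interaction score per the labels, a weighted p-value on a log scale that the authors computed per pair of fragments, and it was not normalised between conditions here. A deposited distance column in bp was used for contacts within chromosomes. Coordinates were on GRCh38 according to the submitters' processing notes. The read aligner, the version of the caller, the fragment binning and the filters were not given in the sources used here. Read depth per library was unknown. The matrix was checked for its lowest maximum score per contact (5.00), and 77.2% of all scores were 0.

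A contact was called at a score of 5 or more. Pairs of conditions were compared by gained, lost and kept contacts, by the Jaccard index and by Spearman correlation across contacts. Shares were given with Wilson 95% intervals. Baits joined by contacts within chromosomes were grouped as connected components. With 1 pooled value per condition no test between conditions was run. Correlation with the day over the 7 time points used two-sided exact permutation tests of Pearson's r and Spearman's rho, adjusted by Benjamini-Hochberg over 18 measures, and the smallest p possible was 0.000397. Contacts were also classed over the time points as kept, gained, lost or transient, and the class counts were set against all 5040 orders of the time points.

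Protein-coding genes were taken from the reference annotation (GRCh38, 19961 genes after 95 readthrough genes were left out). That annotation held no strand, so a gene was linked to a contact where either of its annotated ends lay in the bait or other-end interval widened by 1 kb, in place of the planned transcription start site. This linked 18610 genes, 11293 of them within chromosomes and 9445 at the other end within chromosomes. Sex chromosome Y genes and contacts were left out of the gene and contact lists. The 13 gene lists were naive, primed and general pluripotency, neuroectoderm, definitive endoderm, mesoderm, neural crest, trophectoderm and amnion, HOX, other developmental transcription factors, signalling, Polycomb and housekeeping genes. A gene may stand in several lists. The change in a list's mean number of contacts was placed among 10000 random lists of equal size drawn within 10 bins of contact number, as a description. Contact number was a gene's mean over all 10 conditions, so it included those compared and the many calls of DE and NE. The bins were coarse, and the random lists held fewer contacts than most lists (HOX 10.4 per gene and condition against 7.08 over all contacts, and 6.47 against 3.18 within chromosomes). Random lists drawn from the 20 genes nearest in contact number to each member, added after seeing the data, came closer (10.4 and 6.29, but 2.80 against 3.21 for HOX at the other end). Counts within chromosomes and with the gene at the other end were added after seeing the data.

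The named genes were, for each of the comparisons with day 14, the 3 genes per list with the largest absolute change in called contacts, the 5 genes with the largest gain and the 5 with the largest loss. PAX6, SOX1, SOX17, GATA6, KLF17 and HOXA9 were added in every condition, and the 3 contacts with the largest gain and loss in asinh(score) were taken. The text gives a part of these, often with their contacts within chromosomes. The lists, the comparisons and this rule were fixed before the data were examined. The placement of lists was tested on simulated data with lists of 30 genes. Without an added effect 4% of 100 lists lay outside the central 95%. With 0.5, 1 and 2 contacts added per gene, 44%, 88% and 100% of 50 lists lay at percentile 97.5 or above. The simulated counts were independent between genes, which were picked at random and matched on the simulated conditions only. Members of the real lists share contacts, so the 4% does not give their error rate.

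Alternatives were score thresholds of 3 and 10, quantile-normalised scores, an equal number of top-scoring contacts per condition, contacts within chromosomes only, no bait-to-bait contacts, each listed pair counted once, a margin of 1 in score, other ends within 10 kb taken as shared, each bait counted once, other gene links and 40 matching bins. Python 3.11.15 was used with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1, networkx 3.6.1 and matplotlib 3.10.9.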

Results

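Poised enhancers are regulatory elements that carry Polycomb marks in pluripotent cells and lie near genes of later development. Contacts of 28903 captured fragments, called baits, were measured by Poised Enhancer Capture Hi-C, which enriches ligation products that have a bait at an end. The capture was designed for poised enhancers, but 12 baits were mitochondrial, so not every bait is one. The 20 libraries covered 10 conditions with 2 libraries each. HNES1, a human naive embryonic stem cell line, was sampled in the naive state and at 6 later points of its transition to the primed state, which were day 1, day 3, day 5, day 7, day 10 and day 14. Cells at day 14 were also differentiated to definitive endoderm (DE) and to neuroectoderm (NE), and the primed embryonic stem cell line H9 was sampled as well. The labels gave 10 days of differentiation for NE and no duration for DE. The values were interaction scores for 766138 contacts between a bait and another fragment, with 1 score per condition that pooled both libraries. No spread between replicates and no test between conditions could therefore be had. The file gave no read counts, so the depth per library was unknown, and the 95% Wilson intervals printed here cover counting error only. A contact was taken as called in a condition at a score of 5 or more.

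How many contacts the baits made in each state was the first question. Naive cells had 48038 called contacts, day 14 cells 51930 and H9 cells 62210, while DE had 217055 and NE 187963. Over the transition the number lay between 43741 at day 1 and 54523 at day 3. Contacts within chromosomes numbered 18272 in naive cells, 20498 at day 14, 23764 in H9, 29563 in DE and 32672 in NE. Contacts between chromosomes made up 60.5% of the calls at day 14 (interval 60.1 to 60.9), 86.4% in DE (86.2 to 86.5) and 82.6% in NE (82.4 to 82.8). At a score of 10 or more, DE had 0.920, NE 0.837 and naive cells 1.67 times the calls of day 14, which was due to contacts between chromosomes. Within chromosomes DE and NE kept their excess at that score, with 809 and 1043 contacts against 420 at day 14 and 335 in naive cells. Every listed contact reached a score of 5 somewhere, and 96.5% did so in 1 condition only (85.8% within chromosomes).

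**Figure D1:**
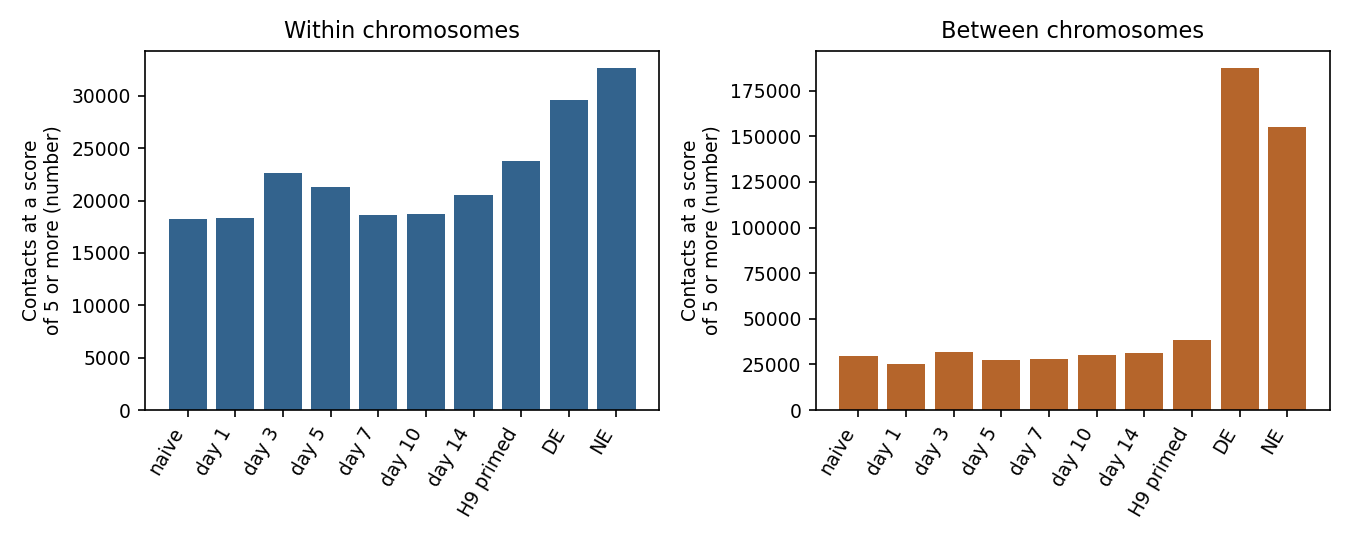
Bars give the number of contacts at a score of 5 or more in each of the 10 conditions, within chromosomes (left) and between chromosomes (right), with 1 pooled value per condition. DE and NE stand apart mainly between chromosomes, with 187492 and 155291 contacts against 31432 at day 14.

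Baits near OTP, a homeobox gene of hypothalamic neurons on chromosome 5 (77628712 to 77638713, GRCh38), formed the largest group of linked baits at days 3, 5, 7 and 14 and in H9. Within 400 kb of OTP, 7 pairs of baits were called in naive cells, 21 at day 14 and 22 in H9, against 4 in DE and 4 in NE. The course was uneven, with 22 pairs at day 3, 12 at day 5, 14 at day 7 and 4 at day 10. Near HOXA9, a HOX gene of posterior patterning, 4 pairs were called in naive cells, 8 at day 14, 8 in H9, 5 in DE and 3 in NE, with 10 at day 7 but 3 at day 10. Baits around MEIS2, a partner of HOX proteins, formed groups of 8 baits at day 14 and 13 in DE. A group around FOXD1, a forkhead gene of the kidney stroma, held 11 baits in H9. These regions were chosen after their values were seen.

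Contacts from bait to bait within chromosomes numbered 130 in naive cells, which was 0.711% of the contacts within chromosomes (interval 0.600 to 0.844). Day 14 had 324 (1.58%, interval 1.42 to 1.76), H9 434 (1.83%, 1.66 to 2.00), DE 385 (1.30%, 1.18 to 1.44) and NE 389 (1.19%, 1.08 to 1.31). Unlike the pairs near OTP and HOXA9, these are listings, and a pair can be listed from each of its baits. Contacts per gene, over all contacts and within chromosomes, are listings too. A bait pair listed from both baits therefore counts once per listing for a gene at either end. Over all contacts 3558 of the 9592 bait-to-bait listings were second listings of a pair. Groups of at least 3 linked baits numbered 8 in naive cells, 29 at day 14, 42 in H9, 36 in DE and 35 in NE. Distances of 100 kb to 1 Mb held 84.4% of the contacts within chromosomes in naive cells and 81.7% at day 14. A bait with a call within chromosomes had 1.71 such contacts in naive cells, 1.83 at day 14, 1.93 in H9, 2.12 in DE and 2.24 in NE.

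**Figure D2:**
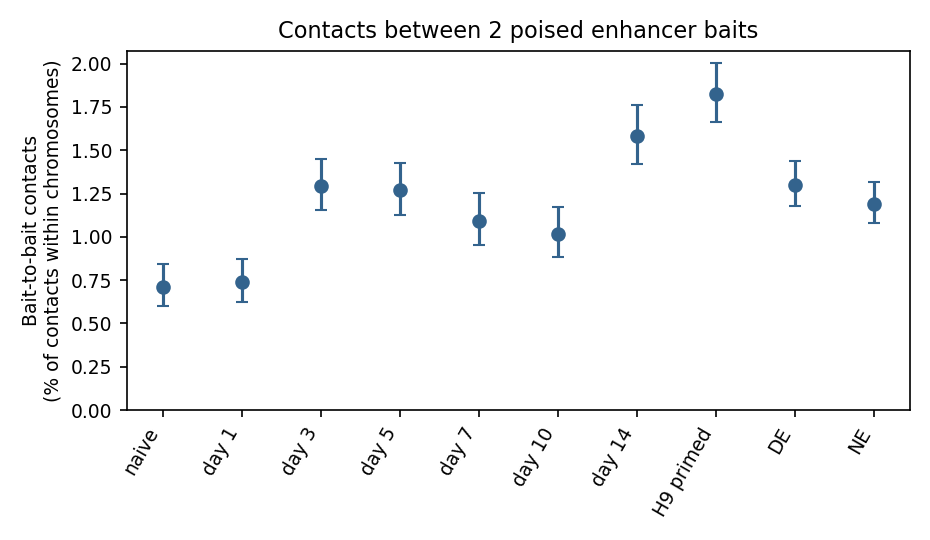
Points give the share of contacts within chromosomes that joined 2 baits, in percent, for each condition, and bars give the 95% Wilson interval, which covers counting error only. Naive and day 1 cells sit lowest at 0.711% and 0.737%, and H9 highest at 1.83%.

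**Figure D3:**
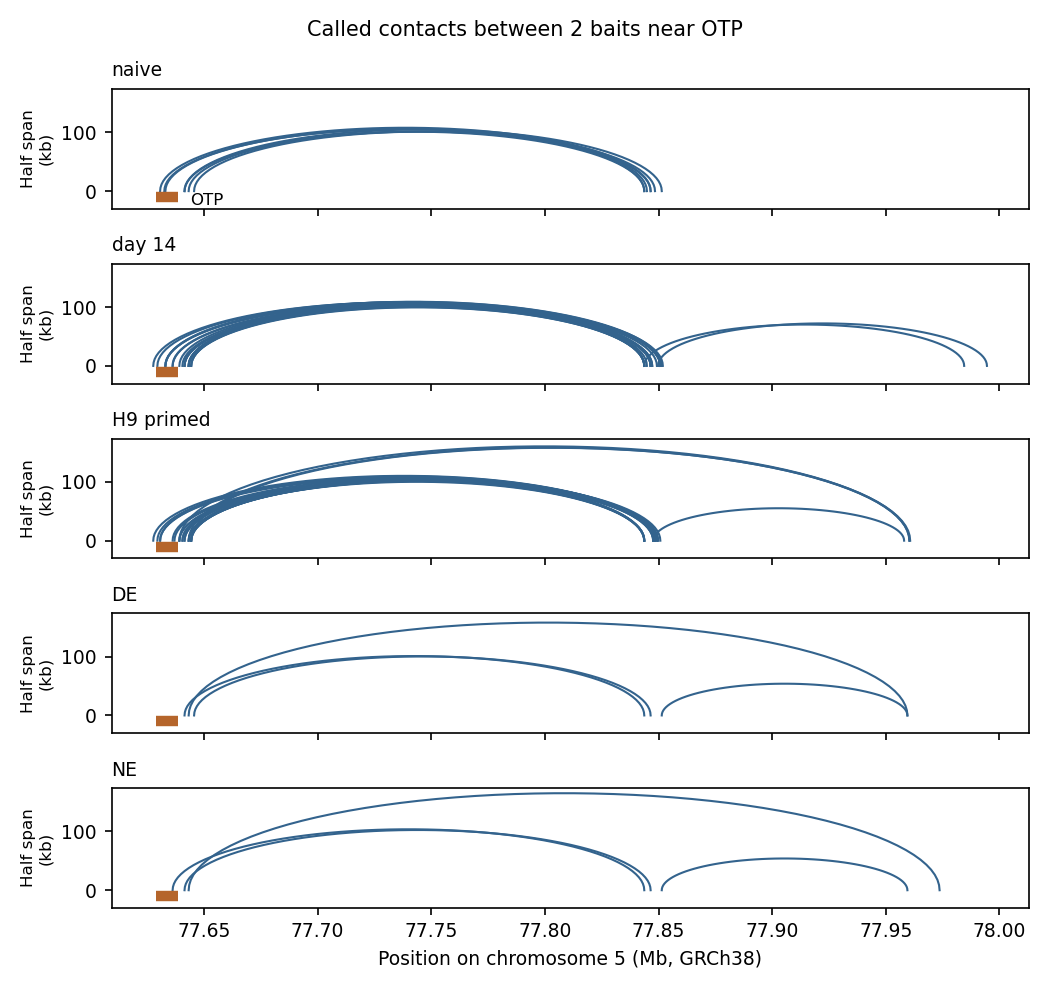
Arcs join the midpoints of 2 baits with a called contact near OTP (orange bar) in 5 conditions, against the position on chromosome 5 in Mb, and the arc height is 0.5 times the distance in kb. Naive cells show 7 arcs, day 14 shows 21, H9 shows 22, and DE and NE show 4 each.

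The comparison of naive with day 14 cells asked which genes had more bait contacts in the primed state. HOX genes, which pattern the body axis, had a mean of 3.10 contacts within chromosomes in naive cells and 8.33 at day 14, and 34 of the 39 had more, 3 fewer and 2 the same number. Other developmental transcription factor genes had means of 1.51 and 2.81, with 61 of 140 having more, 28 fewer and 51 the same. With the gene at the other end, so that a distant bait was in contact with the gene itself, the means were 1.08 and 4.22 for HOX genes. For the other developmental transcription factor genes they were 0.277 and 1.29. NKX2-1, a regulator of forebrain and lung development on chromosome 14 (36516397 to 36520232), had 0 contacts in naive cells and 12 at day 14, all with the gene at the other end.

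Neuroectoderm genes had a mean of 1.47 contacts within chromosomes in naive cells and 3.25 at day 14. Among them SIX6, an eye and forebrain gene, had 2 and 20, and MEIS2 had 5 and 15. Among mesoderm genes, with means of 1.38 and 2.71, ISL1, a gene of cardiac progenitors and motor neurons, had 5 and 23, and MYOD1, a regulator of muscle, had 3 and 10. The trophectoderm and amnion genes had means of 2.00 and 4.70, and CDX2 had 2 and 10. OTP had 1 and 14, HOXA2 4 and 18, HOXB13 2 and 12, and HOXA9 6 and 17. Definitive endoderm genes had means of 1.37 and 2.00, with 7 members having more and 7 fewer, and SOX17, a regulator of endoderm, had 3 and 10 while PRDM1 had 2 and 1. Neural crest genes had means of 1.73 and 1.45, signalling genes 1.21 and 1.67, and Polycomb genes 1.33 and 2.00, among them PHC2 with 3 and 10.

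Naive pluripotency genes had means of 0.714 and 1.14, primed pluripotency genes 0.923 and 1.46, and general pluripotency genes 0.333 and 0.111. TFCP2L1, a naive factor, had 0 and 3 contacts within chromosomes, and FZD7, a WNT receptor gene on the primed list, had 4 and 10. Housekeeping genes had means of 0.421 and 0.211, and all linked genes 0.586 and 0.718. PAX6, a regulator of eye and neural development, and KLF17, a naive factor, had 0 contacts at both times, SOX1 had 1 and 1, and GATA6 had 2 and 1. Over all genes, the largest gains counting contacts between chromosomes were NBPF1 (51 to 73), ZNF385A (17 to 39), ISL1 (10 to 30), LAG3 (6 to 25) and SIX6 (9 to 25). ZNF664 (14 to 2), TMOD2 (14 to 3), KIAA1549 (13 to 2), PLEKHA2 (21 to 10) and ADAMTS8 (19 to 9) had the largest losses.

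**Figure D4:**
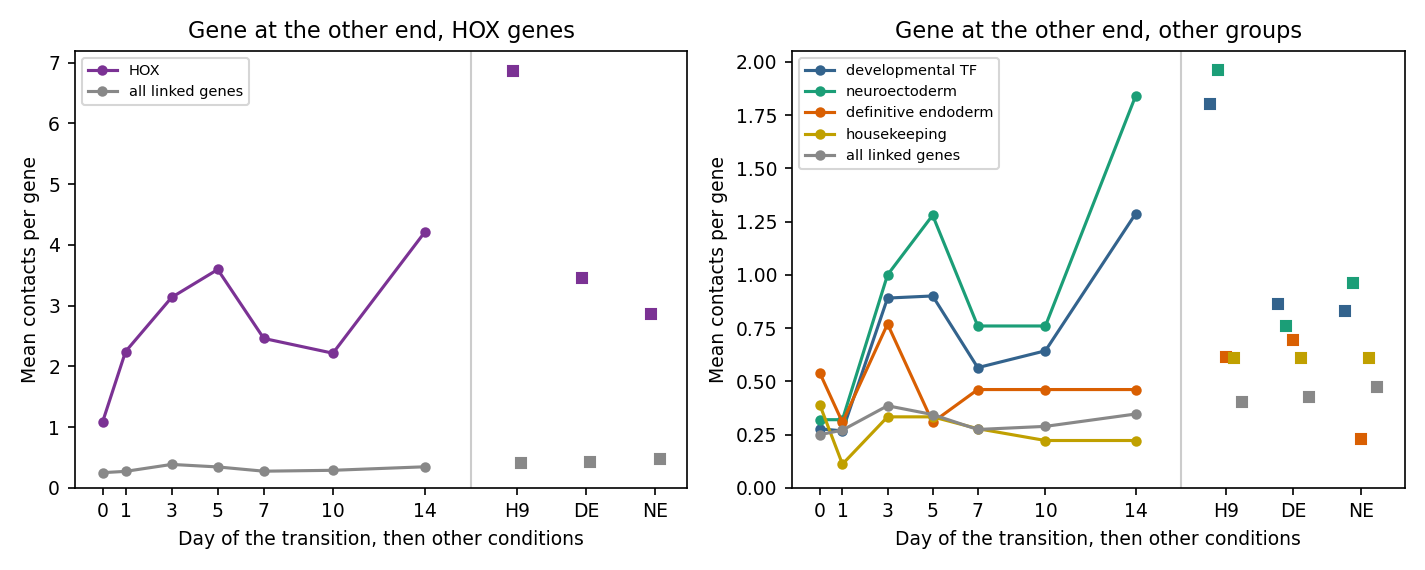
Mean contacts per gene within chromosomes, with the gene at the other end, are plotted against the day of the transition (circles and lines), then for H9, DE and NE (squares), for HOX genes (left) and other groups (right). HOX genes go from 1.08 in naive cells to 4.22 at day 14 and 6.86 in H9, and lie at 3.46 in DE and 2.86 in NE.

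Set against 10000 random lists drawn within 10 bins of contact number, as a description and not a test, 4 of the 13 lists had a larger change from naive to day 14 than the central 95% of random lists. These were HOX, other developmental transcription factors, neuroectoderm, and trophectoderm and amnion, and mesoderm joined them within chromosomes (percentile 98.0). None lay under that range. The random lists had fewer contacts than the lists (7.08 against 10.4 for HOX, 5.67 against 7.80 for neuroectoderm, 4.56 against 6.79 for trophectoderm and amnion), which by itself can give a larger change. Drawn from the 20 nearest genes in contact number they had 10.4, 7.59 and 6.61, and HOX (percentile 100), other developmental transcription factors (99.9) and trophectoderm and amnion (99.5) stayed above the range. Neuroectoderm lay at 95.2 over all contacts and 99.0 within chromosomes, and mesoderm at 92.6 within chromosomes. Without the gene that moved a list most, a choice that tends to lower a list, HOX and the other developmental transcription factors stayed above the range. Trophectoderm and amnion rested on ISL1 and CDX2, at percentile 94.8 over all contacts and 82.4 within chromosomes without ISL1, and 39.9 within chromosomes without both. Mesoderm rested on ISL1 (74.3 within chromosomes without it), and neuroectoderm lay at 93.2 over all contacts without SIX6. Within chromosomes neuroectoderm stayed above without SIX6 but lay at 89.8 without SIX6 and NKX2-1, and at the other end it lay at 98.4 without both. The contacts that differed were 50651 gained, 46759 lost and 1279 kept, or 19255, 17029 and 1243 within chromosomes, and at a score of 10 losses outnumbered gains over all contacts (6796 against 4047), while calls within chromosomes were 335 in naive cells and 420 at day 14. The strongest losses within chromosomes joined a bait at TBR1, a cortical neuron gene, to TANK (score 13.0, then 0) and a bait at HES7, a gene of somite segmentation, to NAA38 (13.0, then 0). At a score of 10 the HOX change lay inside the random range, at percentile 16.0, and so did that of the other developmental transcription factors, at 96.7. List members share contacts, so they are not independent.

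Along the transition, HOX genes at the other end had means of 1.08, 2.24, 3.14, 3.59, 2.46, 2.22 and 4.22 from the naive state to day 14, with lower values at days 7 and 10 than at days 5 and 14. Contacts that were absent early and called at days 10 and 14 numbered 854 within chromosomes. Of these, 20 (2.34%, interval 1.52 to 3.59) involved developmental transcription factor genes and 17 (1.99%, 1.25 to 3.16) HOX genes, against 1.47% and 0.656% among contacts in no class. ISL1 took part in 4, and HOXA9 and HOXA10 in 3 each. Contacts called early and absent late numbered 638, of which 2 (0.313%, interval 0.0860 to 1.14) involved developmental transcription factor genes and 12 (1.88%, 1.08 to 3.26) HOX genes, among them HOXC11 with 3. Transient contacts numbered 2608, with 46 (1.76%) at developmental transcription factor genes and 43 (1.65%) at HOX genes. Another 285 were called at 6 or all 7 time points, with 2.11% and 1.40%. Every class needs at least 2 calls, which contacts in no class do not. Higher shares than in that group therefore cannot be told apart from recurrence of the calls.

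Of the 5040 orders of the 7 time points, 552 gave as many gained contacts within chromosomes as the real order, 3552 as many lost and 1280 as many transient. None of the 18 measures followed the day past an adjusted p of 0.05 in two-sided exact permutation tests of correlation. The smallest raw p belonged to primed pluripotency genes (Spearman's rho 0.821, exact p 0.0341, adjusted 0.605, and Pearson's r 0.647, exact p 0.120, adjusted 0.523). HOX genes had r 0.647 (exact p 0.119, adjusted 0.523) and rho 0.714 (exact p 0.0881, adjusted 0.605), and r was 0.00794 without the naive state and day 14, so the relation rested on these. Neighbouring times shared few calls within chromosomes, with a Jaccard index of 0.0338 for naive and day 1 against 0.0331 for naive and day 14.

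The comparison with H9 asked how day 14 HNES1 cells relate to an established primed line. HOX genes had a mean of 8.33 contacts within chromosomes at day 14 and 10.9 in H9, with 28 of 39 having more and 8 fewer. Other developmental transcription factor genes had 2.81 and 3.56, with 71 of 140 having more and 32 fewer. HOXB9, a gene of posterior patterning on chromosome 17 (48621156 to 48626358), had 11 and 32, HOXC11 10 and 21, and HOXA4 4 and 11. PAX2, a regulator of kidney development, had 5 and 12, FZD7 10 and 21, and OTX2, a forebrain gene, 1 and 4.

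Mesoderm genes had means of 2.71 and 3.88 and neural crest genes 1.45 and 3.64, both above the central 95% of random lists within chromosomes, though mesoderm lay at percentile 94.1 without PAX2 and at 94.4 against the nearest genes. Neuroectoderm genes had 3.25 and 3.94, definitive endoderm genes 2.00 and 1.89, signalling genes 1.67 and 2.10, Polycomb genes 2.00 and 2.00, and housekeeping genes 0.211 and 0.579. For the trophectoderm and amnion genes the means were 4.70 and 5.20, for naive pluripotency genes 1.14 and 0.857, for primed 1.46 and 2.69 and for general 0.111 and 0.444. Fewer contacts in H9 were found at NEUROG1, a neurogenic factor (14 and 6), and EVX2, a homeobox gene beside the HOXD cluster (13 and 4). Over all genes the largest gains included the mitochondrial genes COX1 (14 to 61), ND2 (12 to 40) and COX2 (7 to 37), with 0 contacts within the mitochondrial chromosome in H9, and CNPY1 (7 to 28). KCNA5 (37 to 19), NBPF1 (73 to 56) and LAG3 (25 to 8) were among the largest losses.

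Between day 14 and H9, 22002 contacts within chromosomes were gained, 18736 lost and 1762 kept, and over all contacts the counts were 60411, 50131 and 1799. At a score of 10 the order of gains and losses over all contacts turned, with 3681 gained and 4042 lost, while calls within chromosomes were 420 at day 14 and 610 in H9. The Jaccard index within chromosomes was 0.0415 for H9 and day 14, 0.0318 for H9 and naive cells, 0.0466 for H9 and DE and 0.0480 for H9 and NE. The Jaccard index also depends on the number of calls, which was larger in DE and NE. Across contacts within chromosomes, which are not independent replicates, Spearman's rho of scores with H9 was 0.203 for day 14. It was 0.185 for DE, 0.178 for NE and 0.173 for naive cells. For days 1, 3, 5, 7 and 10 it was 0.181, 0.178, 0.174, 0.189 and 0.191, so it did not rise evenly with the day. When the same number of top-scoring contacts was called per condition, the changes of HOX and other developmental transcription factor genes lay inside the random range (percentiles 53.5 and 93.2). With the same number of contacts within chromosomes and the gene at the other end they lay above it, with means of 3.70 and 5.57 for HOX (percentile 100) and 1.18 and 1.44 for the others (98.3, but 96.5 against the nearest genes). Cell line and culture differed together in this comparison.

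The comparison of DE with day 14 asked how contacts differed after entry into endoderm. Within chromosomes, definitive endoderm genes had a mean of 2.00 contacts at day 14 and 3.84 in DE, and 11 of 19 had more and 2 fewer, while all linked genes had 0.718 and 0.955. EOMES, a driver of mesendoderm on chromosome 3 (27715953 to 27722713), had 3 and 13, GATA4, an endoderm and heart factor, 3 and 11, SOX17 10 and 14, and PRDM1 1 and 3. HOX genes had 8.33 and 7.36, with 15 of 39 having more and 21 fewer, and HOXA9 had 17 and 5. NKX2-1 had 12 and 1, EVX1, a homeobox gene beside the HOXA cluster, 9 and 0, and HOXA11 7 and 1.

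Primed pluripotency genes had means of 1.46 and 3.92, among them FZD7 with 10 and 37. Neuroectoderm genes had 3.25 and 3.91, other developmental transcription factor genes 2.81 and 3.28, mesoderm 2.71 and 4.04, neural crest 1.45 and 3.45, signalling 1.67 and 2.62 and Polycomb genes 2.00 and 1.61. SNAI2, a regulator of neural crest migration, had 0 and 11, and DKK1, a WNT antagonist, 10 and 23. Trophectoderm and amnion genes had 4.70 and 4.00, naive pluripotency genes 1.14 and 2.29, general pluripotency genes 0.111 and 0.667, and housekeeping genes 0.211 and 0.632. With the gene at the other end, the means were 1.84 and 0.760 for neuroectoderm genes and 1.29 and 0.861 for other developmental transcription factor genes. Counting contacts between chromosomes, SOX14 had 8 and 81, INSYN2B 27 and 97, ZFR 15 and 82, VAX1 10 and 74 and ANKRD34A 18 and 80, but within chromosomes SOX14 had 3 and 6, INSYN2B 12 and 13, ZFR 1 and 1, VAX1 6 and 11 and ANKRD34A 4 and 10.

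Over all contacts 4 lists lay above the central 95% of random lists and HOX below it. HOX means were 10.1 and 20.4, with 35 genes having more and 3 fewer, but random lists gained more (median 13.5 against 10.3). The contact number used for matching included DE. A list with relatively many contacts in other conditions then has a smaller change toward DE by construction. The 4 were neuroectoderm, definitive endoderm, mesoderm and other developmental transcription factors, but none lay above with any part of the gene or with each bait counted once, where neuroectoderm lay below (percentile 1.64). The random lists held fewer contacts than these lists (5.66 against 7.80 for neuroectoderm), which by itself can give a larger change. Against the nearest genes in contact number only definitive endoderm (99.9) and other developmental transcription factors (99.7) stayed above. Neuroectoderm (92.1) and mesoderm (95.6) did not, and HOX stayed below. No list lay below with the gene end within 5 kb, with summed asinh(score) or at a score of 10. Within chromosomes, primed pluripotency (percentile 99.8) and definitive endoderm (98.5) lay above and HOX below, and the first rested on FZD7 (56.3 without it) and the second lay at 94.8 without EOMES. With the gene at the other end HOX, neuroectoderm and other developmental transcription factors lay below, and general pluripotency above (98.3). Of these, HOX (4.13) and general pluripotency (96.6) lay inside the range against the nearest genes. So did neuroectoderm without NKX2-1 and SIX6 (3.79) and HOX without HOXA10 and HOXC13 (3.72) in the bins. Other developmental transcription factors stayed below without NKX2-1 and SIX6 (0.145). With an equal number of contacts within chromosomes per condition, HOX means at the other end were 3.70 at day 14 and 2.22 in DE. In that setting HOX lay below the range in the bins (percentile 0) and against the nearest genes (1.39). The direction for neuroectoderm and developmental transcription factor genes thus turned with the contacts counted. Gained contacts numbered 214954, lost 49829 and kept 2101, or 27506, 18441 and 2057 within chromosomes, and at a score of 10 there were 3700 gained and 4029 lost over all contacts, against 420 calls at day 14 and 809 in DE within chromosomes. The largest gain within chromosomes was a pair on chromosome 16, from 0 to 24.1. This pair was also called in naive cells (8.60), at days 3, 5 and 7 (8.73, 11.5 and 11.5) and in NE (22.7). A bait on chromosome 15 (77543409 to 77544105) reaching PEAK1 had the score 0 at day 14 and 21.1 in DE. That contact was also called at day 3 (8.46), in H9 (6.90) and in NE (5.09).

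The comparison of NE with day 14 asked the same for the neural lineage. Within chromosomes, neuroectoderm genes had a mean of 3.25 contacts at day 14 and 3.88 in NE, with 19 of 32 having more and 6 fewer. All linked genes had 0.718 and 1.08, and random lists had a median change of 1.03 against 0.625 for this list (percentile 19.6), so the list gained no more than comparable genes. LHX2, a forebrain and eye gene on chromosome 9 (124011768 to 124033301), had 0 and 7, SIX3, a forebrain gene, 3 and 8, and NEUROG1 14 and 17. HOX genes had 8.33 and 6.92, with 13 of 39 having more and 21 fewer. HOXA2 had 18 and 5 and HOXA9 17 and 7, while HOXC5 had 14 and 22. NKX2-1 had 12 and 1, as in DE.

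Definitive endoderm genes also had more in NE, with means of 2.00 and 3.58, among them EOMES with 3 and 10 and SOX17 with 10 and 17. The means were 2.81 and 3.59 for other developmental transcription factor genes, 2.71 and 3.33 for mesoderm, 1.45 and 3.55 for neural crest, 1.67 and 2.69 for signalling and 2.00 and 2.11 for Polycomb genes. MSX2, a neural crest gene, had 2 and 10, and SNAI2 0 and 11. Trophectoderm and amnion genes had 4.70 and 4.50, primed pluripotency genes 1.46 and 2.69, naive 1.14 and 1.29, general 0.111 and 0.667 and housekeeping genes 0.211 and 0.579. With the gene at the other end, the means were 1.84 and 0.960 for neuroectoderm genes, 1.29 and 0.832 for other developmental transcription factor genes and 4.22 and 2.86 for HOX genes. CBX2, a Polycomb gene, had 19 and 79 contacts over all but 6 and 6 within chromosomes, PRTG had 10 and 67 over all and 3 and 15 within, and SOX1, a neural gene, had 1 and 11 over all and 1 and 1 within.

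Over all contacts neuroectoderm, definitive endoderm, Polycomb and other developmental transcription factor genes lay above the random range and HOX below. HOX means were 10.1 and 17.5, a change of 7.46 against a random median of 11.2. The limit of the matching given for DE holds for NE too. The random lists held fewer contacts than the lists above the range (5.67 against 7.80 for neuroectoderm, 2.77 against 3.73 for Polycomb). Against the nearest genes in contact number only definitive endoderm stayed above (97.6). Neuroectoderm (76.7), Polycomb (80.7) and other developmental transcription factor genes (69.1) did not, and HOX stayed below. With the gene end within 5 kb no list lay below. None lay above with 40 matching bins, any part of the gene or each bait counted once, and in the last setting neuroectoderm and other developmental transcription factors lay below (percentiles 2.13 and 0.02). Polycomb genes lay at 61.2 without CBX2 and below the range, at 1.21, with top-scoring contacts. Neuroectoderm lay at 94.1 without NEUROG1 and definitive endoderm at 96.6 without EOMES. Within chromosomes none lay above and HOX below. With the gene at the other end none lay above, and HOX, neuroectoderm and other developmental transcription factors lay below. Neuroectoderm rested on NKX2-1 and SIX6, and lay inside the range without both (8.4). HOX without HOXA3 and HOXA10 (0.01) and other developmental transcription factors without NKX2-1 and SIX6 (0) stayed below. Gained contacts numbered 185589, lost 49556 and kept 2374, or 30373, 18199 and 2299 within chromosomes, and at a score of 10 there were 3348 gained and 4019 lost over all contacts, against 420 calls at day 14 and 1043 in NE within chromosomes. A bait at OLFM1, a neuronal gene on chromosome 9, gained the score 21.3 from 0 with a fragment at 135342246 to 135347279.

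The last comparison set both lineages against each other. The length of differentiation was not given for DE, so it cannot be told apart from lineage here. Over all contacts mesoderm (percentile 99.8) and other developmental transcription factors (99.8) lay above the random range in DE relative to NE and Polycomb genes below it (2.28). The first 2 stayed above without the gene that moved them most (98.8 and 98.7), and Polycomb genes did not stay below (10.6). Without 2 genes each, mesoderm (94.8) and other developmental transcription factors (97.2) lay inside the range. No list lay above with the gene end inside the interval or with each bait of a gene counted once. With the gene at the other end HOX lay above (99.9, and 99.4 without HOXC4). Within chromosomes, mesoderm genes had a mean of 4.04 contacts in DE and 3.33 in NE, primed pluripotency genes 3.92 and 2.69, and HOX genes 7.36 and 6.92, all above the random range. Of these within chromosomes none stayed above it without the gene that moved it most, with primed pluripotency at percentile 78.5 without FZD7, mesoderm at 95.6 without PAX2 and HOX at 96.5 without HOXC11 (94.6 against the nearest genes). Definitive endoderm genes had 3.84 and 3.58, and neuroectoderm genes 3.91 and 3.88. FZD7 had 37 contacts in DE and 23 in NE, EOMES 13 and 10, and SOX17 14 and 17. Within chromosomes 24687 contacts absent at day 14 were called in DE only, 27554 in NE only and 2819 in both, and 17066 of the 20498 day 14 contacts were called in neither. The shared gains were 0.546 times the number independence would give, a ratio that is low by construction, and with day 10 in place of day 14 it was 0.557. Between chromosomes, 206 contacts were called in both lineages.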

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

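The lists that moved in opposite directions from day 14 to DE and from day 14 to NE are given here, the counts within chromosomes and at the other end were added after the data were seen, and no difference was tested. Definitive endoderm genes at the other end of contacts within chromosomes differed by 0.462 contacts per gene between the changes (0.231 in DE and -0.231 in NE). With an equal number of contacts within chromosomes per condition their mean went from 0.462 at day 14 to 0.308 in DE and 0.0769 in NE, so the directions were no longer opposite. Mesoderm genes at the other end differed by 0.412 (0.353 in DE and -0.0588 in NE), and with equal numbers the mean went from 0.706 to 1.00 in DE and 0.647 in NE, still opposite. Polycomb genes within chromosomes differed by -0.500 (-0.389 in DE and 0.111 in NE). Primed pluripotency genes at the other end differed by -0.182 (-0.0909 in DE and 0.0909 in NE), and signalling genes by 0.0606 (0.0303 in DE and -0.0303 in NE). At the other end 13 definitive endoderm, 17 mesoderm, 11 primed pluripotency and 33 signalling genes were linked. These differences therefore rest on few contacts.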

How the results depend on the processing

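No paired analysis was possible because both replicates of a condition were pooled into 1 column. For the same reason leaving out each replicate and a replicate block could not be run. Of 297 recomputed summary results 186 kept their size and side and 111 did not, and the cause was not tested unless named. Of 60 counts of contacts per condition 38 were kept, and of 845 list percentiles 699. None of 160 recomputed correlations with the day passed an adjusted p of 0.05, the smallest being between 0.306 (without day 3) and 1, but Spearman's rho turned in sign in 11. Of 1592 changes of named genes 136 turned in sign, from 0 of 199 without the 71 contacts between HOX cluster baits to 41 of 199 with top-scoring contacts. The alternatives for lists at any part of the gene, at the other end, within chromosomes, with 40 bins, from the nearest genes, at a score of 10, with top-scoring contacts and without the genes that moved a list most, and for calls within chromosomes at a score of 10, were chosen after seeing the data. Other alternatives, with bait-to-bait contacts left out, pairs counted once, a margin or nearby other ends, kept the size and side of every summary result recomputed under them. They covered only calls per condition, gains, losses and temporal classes. No gene list was recomputed under them, so they do not show whether the list changes hold without all bait-to-bait contacts. The unknown depth limits every count.

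At a score of 10, calls relative to day 14 were 1.67 in naive cells, 0.920 in DE and 0.837 in NE, but within chromosomes DE had 1.93 times the 420 calls of day 14, NE had 1043 calls and naive cells 335, so the turn came from contacts between chromosomes. Gained and lost contacts were then 4047 and 6796 from naive to day 14, 3681 and 4042 for H9, 3700 and 4029 for DE, 3348 and 4019 for NE, and 3553 and 3211 from NE to DE. Temporal classes at 10 held 39 kept, 31 gained, 20 lost and 74 transient contacts, and at a score of 3 they held 1992, 4217, 3190 and 12114. A stricter threshold leaves fewer contacts by construction.

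With quantile-normalised scores, calls relative to day 14 were 0.994 in DE and 1.00 in NE, which that step makes equal by construction. Gained contacts were 50650 in DE and 51007 in NE, and from NE to DE 50652 were gained and 51060 lost. The classes held 489 kept, 2011 lost and 5195 transient contacts. With 43741 top-scoring contacts per condition, gained contacts were 42974 in DE and 42933 in NE, 42839 were gained and 42839 lost from NE to DE, and 528 were in the gained class.

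Within chromosomes only, calls relative to day 14 were 1.44 in DE and 1.59 in NE. Gained and lost contacts were 19255 and 17029 from naive to day 14, 22002 and 18736 for H9, 27506 and 18441 for DE, 30373 and 18199 for NE, and 25820 and 28929 from NE to DE. Counting baits once, those with more and fewer contacts were 9843 and 8591 from naive to day 14, 11641 and 7831 for H9, 26908 and 622 for DE, 25603 and 993 for NE, and 15867 and 9610 from NE to DE. Among contacts called in an HNES1 column H9 gained 5523. Naive and day 1 together against day 10 and day 14 gave 1290 gained and 1004 lost.

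Lists outside the central 95% of random lists changed as follows. With the gene end inside the interval, 2 lay above for naive to day 14, 1 for DE, 1 for NE and 0 from NE to DE, where 0 lay below. With the gene end within 5 kb, 5 lay above for H9, 8 above and 0 below for DE, 0 below for NE, and 5 above and 0 below from NE to DE. With summed asinh(score), 0 lay below for DE and 0 from NE to DE. With each bait of a gene counted once, 4 lay above for H9, 0 above and 2 below for DE, 0 above and 3 below for NE, and 0 and 0 from NE to DE. Neuroectoderm then turned to percentile 1.64 in DE and 2.13 in NE, and other developmental transcription factors to 0.02 in NE.

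With any part of the gene, 0 lay above for DE, 0 above for NE and 0 below from NE to DE. At the other end within chromosomes, 1 lay above and 3 below for DE, 0 above and 3 below for NE, and 1 above and 0 below from NE to DE, and neuroectoderm and other developmental transcription factors turned to percentile 0 in DE and in NE. Within chromosomes only, 4 lay above for H9, 2 for DE and 0 for NE, and 0 below from NE to DE. With 40 matching bins 0 lay above for NE, and with random lists from the 20 nearest genes in contact number 2 lay above for DE and 1 for NE.

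At a score of 10, 1 lay above for naive to day 14, 1 above and 1 below for H9, 1 above and 0 below for DE, 1 above and 3 below for NE and 0 below from NE to DE, with neuroectoderm turned to percentile 0.895 in NE. With top-scoring contacts, 0 lay above for H9, 2 above for DE, 1 above and 2 below for NE, and 4 above and 0 below from NE to DE, with Polycomb genes turned to percentile 1.21 in NE. The HOX change from naive to day 14 was at percentile 100 in all these settings except at a score of 10 (16.0), where HOX genes had a mean level of 0.608 contacts against 10.4 at a score of 5, and that of other developmental transcription factors was at 99.9 or higher except there (96.7).

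Leaving out the gene that moved a list most, a choice that tends to draw a list toward the middle, took several lists into the central 95%. Within chromosomes these were mesoderm (percentile 74.3) and trophectoderm and amnion (82.4) from naive to day 14, mesoderm (94.1) for H9, primed pluripotency (56.3) and definitive endoderm (94.8) for DE, and primed pluripotency (78.5), mesoderm (95.6) and HOX (96.5) from NE to DE. Over all contacts they were neuroectoderm (93.2) and trophectoderm and amnion (94.8) from naive to day 14, neuroectoderm (94.1), definitive endoderm (96.6) and Polycomb genes (61.2) for NE, and Polycomb genes (10.6) from NE to DE. At the other end it was trophectoderm and amnion (94.8) from naive to day 14.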

Other observations

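Of the tests here, those at a score of 10, those with random lists from the nearest genes and that of developmental transcription factor genes with an equal number of top-scoring contacts were chosen after the results they bear on were seen. Contacts with a mitochondrial end, where 12 baits lay, numbered 23 in naive cells, 49 at day 14, 104 in H9, 121 in DE and 109 in NE. Baits on chromosome 12 had 1.41 to 1.55 times the median number of contacts within chromosomes per bait among chromosomes in the time course of HNES1, 1.45 in DE, 1.42 in NE and 1.25 in H9. Pericentromeric baits on chromosome 16, from 34595031 to 46399006 in naive cells, recurred among the largest bait groups. A bait on chromosome 16 (46390065 to 46390538) had 705 contacts between chromosomes and a bait on chromosome 1 (125183675 to 125184134) had 702, against a median of 17, and the latter held 58 of the 150 contacts between chromosomes called in at least 3 conditions.

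DE and NE had 5.66 times the mean number of contacts between chromosomes of the other 8 conditions at a score of 5, but 0.516 times at a score of 10. That value was seen before the comparison was set up, so it restates the pattern, and whether low scores passed the threshold more often in DE and NE for a technical reason stays open. Of the DE contacts between chromosomes 0.110% were called in NE, against 12.7% within chromosomes. Between other conditions the share was about as low, with 0.121% of the naive contacts between chromosomes called at day 14. For day 14 contacts called in H9 it was 0.118%. Contacts between chromosomes thus recurred little anywhere, so the low share cannot decide whether the same pairs form in both lineages. Placement wholly at random, given the contacts per fragment, is argued against, with 165 shared pairs and a mean of 3.39 over 100 shuffles (48.7 times). The excess is 0.0865% of the DE contacts tested and leaves the rest open. Read depth and the background model of the caller in these columns may differ from the others and stay open. A change in cell state stays open too, with the same or different pairs formed in DE and NE.

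Developmental transcription factor genes outside HOX had a mean change of 1.42 contacts from naive cells to day 14, against a median of 0.416 for random lists in 10 bins of contact number and 0.617 for those from the 20 nearest genes (percentile 99.9). With an equal number of top-scoring contacts the change was 0.826 against 0.148 (percentile 99.9), or 0.268 from the nearest genes (99.1), which argues against more calls in every gene as the whole cause. Lists matched on baits within 500 kb left it at percentile 100 (1.42 against 0.349), which argues against bait density at that range as the whole cause. Those lists were matched neither on contact number nor on the baits at the gene itself, so bait density there stays open. Leaving out contacts near HOX genes left it at 100 (1.31 against 0.356, or 0.479 from the nearest genes). The list held no HOX gene and kept 146 of 149 genes, so this step could change little. The change was thus not confined to contacts near HOX genes. A candidate explanation is a gain of poised enhancer contacts at developmental genes in the primed state. That hypothesis was found on the same data and was not itself tested. Replicate spread and depth stay open, and at a score of 10 the list lay inside the random range (percentile 96.7).

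Bait-to-bait contacts within chromosomes were fewer at days 7 and 10 than at days 5 and 14 (0.664 times). With 18272 top-scoring contacts within chromosomes per time point the ratio was 0.725, with 202 and 185 at days 7 and 10 and 235 and 299 at days 5 and 14, which argues against fewer calls as the whole cause. Differences between library batches, which the pooled columns hide, may also give such a dip and stay open, as does a step of the transition itself.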
